A study of Drosophila melanogaster with 16 samples.

How the data were processed

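The series holds 16 libraries of Drosophila melanogaster S2 cells, grown at 25 °C and taken 4 days after control RNAi (GST in the sample titles) or mof RNAi. Per the labels, the cells were given 4-thiouridine at 500 uM for 5 min. TT-seq libraries were made from the purified 4-thiouridine RNA, and total RNA libraries from RNA of cells treated in the same way. There are 4 libraries per RNAi and assay. The question of the series, dosage compensation and transcription initiation in male flies, was taken from its title.

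Per the submitters' processing notes, cutadapt 2.8, STAR 2.7.4a, SAMtools 1.20, featureCounts and DESeq2 were used on build dm6; the notes give no roles, and the strand setting of the counting is not given in the sources used here. The deposited tables hold a signal per gene and library, read counts divided by a DESeq2 size factor, with the factors set separately within each assay's table. Per the labels, spike-in normalised coverage was also made; it was not used here. Every value was tested for whole reads: 100% of the 196547 non-zero values were whole multiples of their library's smallest non-zero value within 0.01. The size factor of TT-seq control replicate 1 lies so close to 1 that this test is weaker for that library. Gene coordinates came from the deposited gene annotation (FlyBase models on dm6). The tables hold 17737 genes, of which 17599 have a symbol in the name table used here. A second deposited annotation, of transcribed regions, was not used. Of 121 named genes, 67 overlap another gene and 55 overlap a gene on the other strand, so that reads of either may be shared if the counting ignored the strand.

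Recovered reads ranged from 10167019 to 15597179 per library in TT-seq and from 21970514 to 38340721 in total RNA. Genes of rRNA took 0.091% to 0.697% of reads and the 10 most counted genes of each library 4.65% to 7.78%. The replicates differed by more than counting error in every pair of libraries (chi-square per gene of at least 8.97), and no library was a copy of another. To measure what these numbers of libraries and reads can show, fold changes were tested on simulated data drawn with the spread of the real libraries. In TT-seq 27% of genes changed 1.5-fold and 76.5% of genes changed 2-fold were recovered, with 3.75 false calls on average. In total RNA these were 68.8%, 80% and 7. The simulated genes varied independently of each other, so spread shared by many genes was left out. Recovery and false calls in the real data may therefore differ.

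Before the data were examined, the tests, the alternatives, the 24 gene lists and the rule for named genes were fixed. Genes with a mean of at least 10 normalised read counts over the 8 libraries of an assay were tested, 9196 in TT-seq and 8971 in total RNA. Values were log2(value + 1) and tested with limma (lmFit, eBayes with trend and robust), mof RNAi against control, with Benjamini-Hochberg adjusted p under 0.05 called. Errors of log2 changes are limma's SE, and other errors are SD between libraries. The index of a chromosome in a library is the median over its tested genes minus the median over tested genes of 2L, 2R, 3L and 3R, after each gene was centred on the mean of the 8 libraries. For an autosomal arm only the other arms were the reference, so the indices of the arms depend on each other. Group differences of indices were tested with two-sided exact permutation tests over the 70 assignments. Shares of calls on the X and the autosomes were compared with two-sided Fisher's exact tests. Lists were tested with camera with a preset correlation of 0.01, again with an estimated correlation and with fry, adjusted over the 24 lists, and their members were counted over all genes tested and adjusted over the list alone. The lists were the MSL complex and roX RNAs, the NSL complex, sex determination, cytosolic and mitochondrial ribosomal proteins, proteasome, oxidative phosphorylation, glycolysis, heat shock, immune genes, small RNA pathway, hemocyte markers, cell cycle, apoptosis and DNA damage, ecdysone response, oxidative and unfolded protein stress, Pol II factors, chromatin acetylation, X-binding factors, and markers of germline, neuron, muscle, fat body and epithelium. Of the listed names, 8 were not found in the annotation.

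Named genes are, in each assay, all members of the MSL list; the 8 largest rises and the 8 largest falls among called genes with a mean of at least 50 and no overlap between the groups' values; up to 3 called members of each other list; and the 5 most counted X genes called lower. Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, centring on the median autosomal gene, TMM factors, edgeR's quasi-likelihood test and DESeq2's Wald test on recovered reads, a block by replicate number, a fold change of at least 1.5, lists without X-linked members, the mean over genes for the index, tertiles for quartiles, and leaving out each library in turn. After the data were seen, a covariate for the slope on the ratio of total RNA to TT-seq reads, the omission of TT-seq control replicates 2 and 3, and the alternatives of the chromosome 4 index were added. With edgeR, 1121 TT-seq genes and 2340 total RNA genes were called, and with DESeq2 1746 and 2596, beside 1042 and 2414 with limma. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.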

Results

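Reads per gene were measured in S2 cells, a cultured Drosophila melanogaster line of male origin, 4 days after RNA interference (RNAi). The trigger was directed at mof or was a control trigger, named GST in the sample titles. Each RNAi was followed by 2 assays with 4 libraries per group, which makes 16 libraries in 4 groups. TT-seq captures the RNA made during a 5 min pulse of 4-thiouridine, and total RNA sequencing counts the RNA present in the cells. Recovered reads per library ranged from 10167019 to 15597179 in TT-seq and from 21970514 to 38340721 in total RNA. The values are normalised read counts with size factors set separately in each assay's table, so every comparison was made inside an assay, and a change shared by all genes could not be seen. The labels do not say that replicates come from separate cultures, so the p-values measure only the spread between these samples.

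The first comparison asks what happened to mof, the RNAi target, and to the other parts of the MSL complex, which binds the male X chromosome and acetylates histone H4. The gene mof (FBgn0014340, dm6 chromosome X, 5873840 to 5876853, minus strand) encodes the acetyltransferase of the MSL and NSL complexes, and it was counted higher, not lower, in the libraries labelled mof RNAi. In TT-seq it had 992 ± 187 normalised read counts in control libraries and 1734 ± 276 in the libraries labelled mof RNAi (SD, n = 4 each), a log2 difference of 0.81 ± 0.15 (SE; adjusted p = 0.0121). In total RNA it had 3346 ± 118 and 7723 ± 3063, a log2 difference of 1.13 ± 0.26 (adjusted p = 0.0237). The noncoding RNA roX2 (FBgn0019660, X, 11579065 to 11580432) is a component of the MSL complex. It fell in total RNA from 12109 ± 1103 to 6666.5 ± 425, by 0.86 ± 0.059 on the log2 scale (adjusted p = 1.24e-09). The other MSL RNA, roX1 (FBgn0019661, X, 3857230 to 3862697), stood at a low level in total RNA. It fell from 47.4 ± 13.3 to 16.7 ± 8.0 normalised read counts, a log2 change of -1.51 ± 0.41 (adjusted p = 0.00769). It overlaps ec on the other strand, and the strand setting of the counting is not stated, so its value is uncertain. In TT-seq neither RNA passed the test. There roX2 had 3142 ± 447 and 2946 ± 284 normalised read counts (log2 difference -0.087, adjusted p = 0.674), and roX1 had a log2 difference of 0.21 (adjusted p = 0.755). The TT-seq change minus the total RNA change of roX2 was 0.79 (exact permutation p = 0.0286, 0.124 after Benjamini-Hochberg adjustment over 13 such differences). That of roX1 was 1.74 (exact permutation p = 0.0571, adjusted 0.159), and that of mof was -0.30 (exact permutation p = 0.457, adjusted 0.54). The smallest value that 70 assignments allow is 0.0286, so 1 difference alone cannot pass the adjustment over 13. The genes msl-1, msl-2, msl-3 and mle, which encode the other protein subunits, did not pass. Their log2 differences lay between -0.057 (msl-2) and 0.21 (msl-3) in TT-seq (adjusted p from 0.371 to 0.817). In total RNA they lay between -0.043 (mle) and 0.068 (msl-2; adjusted p from 0.415 to 0.785). Of the 7 members of the MSL list, 1 rose and 0 fell in TT-seq, and 1 rose and 2 fell in total RNA, also when adjusted over the list alone (list test adjusted p = 0.221 and 0.691). The mof call in total RNA ended without control replicate 1, 2, 3 or 4 (adjusted p = 0.0596, 0.0617, 0.0566 and 0.0579) and without mof RNAi replicate 1 (adjusted p = 0.0592), while the log2 difference stayed at 1.098 to 1.145. The call held without mof RNAi replicate 2, 3 or 4 (0.891, 1.289 and 1.239, adjusted p = 0.00341, 0.0203 and 0.0302), with edgeR (adjusted p = 7.37e-05) and with DESeq2 (adjusted p = 0.000272), but not with a block by replicate number (adjusted p = 0.0781). In total RNA the 4 mof RNAi libraries differed widely in mof, as the plot of mof and roX2 per library shows. In TT-seq the SD of their log2 values was 0.23, against 0.267 in control libraries.

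**Figure D1:**
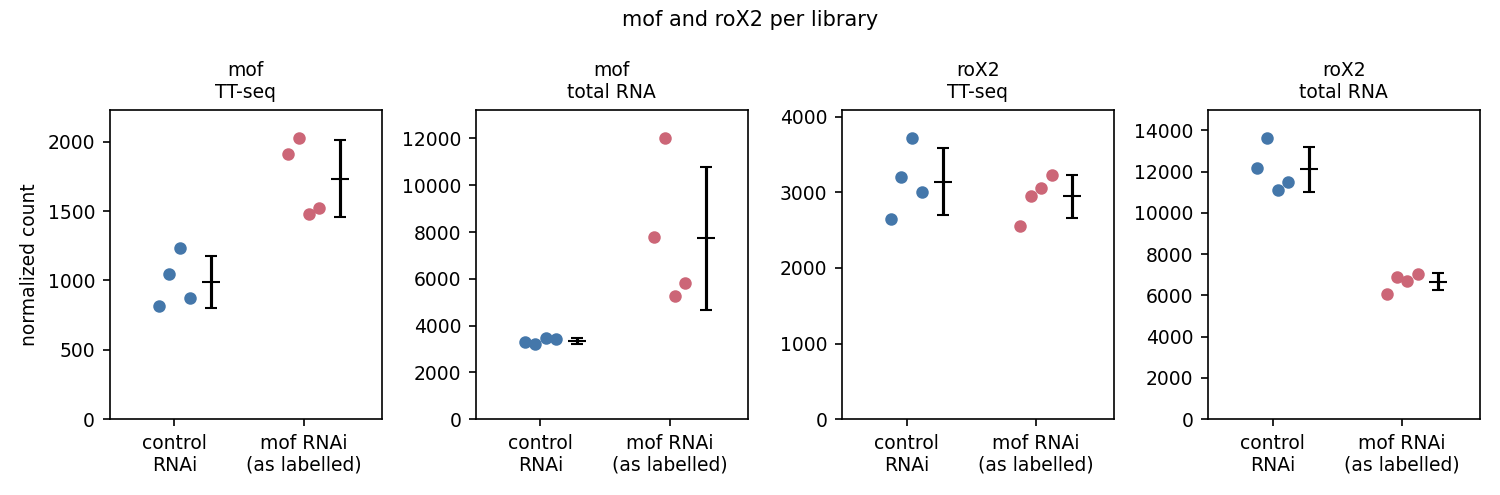
Normalised read counts of mof and roX2 in each control and mof RNAi library of TT-seq and total RNA. Points are libraries and bars mark group means. Mean mof rises from 992 to 1734 in TT-seq and from 3346 to 7723 in total RNA, and mean roX2 in total RNA falls from 12109 to 6666.5.

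The second comparison asks whether X-linked genes changed relative to autosomal genes, since MOF acts on the male X within the MSL complex. X-linked genes were lower under mof RNAi in both assays. In TT-seq, 256 of 1569 tested X genes fell and 45 rose (16.3% and 2.87%). Of 7539 tested genes on 2L, 2R, 3L and 3R, 287 fell and 444 rose (3.81% and 5.89%). In total RNA, 644 of 1563 X genes fell and 80 rose (41.2% and 5.12%). Of 7324 autosomal genes, 639 fell and 1038 rose (8.72% and 14.2%). The excess of autosomal rises depends on the scaling. With each library centred on its median autosomal gene, 827 genes rose in total RNA, 67 of them on the X, and 1560 fell, 738 of them on the X. The median X gene changed by -0.23 in TT-seq and by -0.21 in total RNA on the log2 scale, and the median autosomal gene by 0.005 and 0.033. Below the autosomal median lay 1129 X genes (72%) in TT-seq and 1265 (80.9%) in total RNA. The most abundant X genes that fell in TT-seq included Chc, the clathrin heavy chain (-0.45, adjusted p = 0.042), and svr, a carboxypeptidase (-0.43, adjusted p = 0.0468). The others were pcx (-0.54, adjusted p = 0.0233), c11.1 (-0.53, adjusted p = 0.0415) and CG14438 (-0.70, adjusted p = 0.00691). Those in total RNA were the ribosomal protein genes RpL7A (-0.27, adjusted p = 0.000904), RpL35 (-0.25, adjusted p = 0.000321), RpS28b (-0.22, adjusted p = 0.000724) and RpS5a (-0.16, adjusted p = 0.0094), and Moe, which encodes moesin (-0.12, adjusted p = 0.0451). CG14438 and the ribosomal protein genes kept their calls without any single library. The other genes lost theirs without at least 1 library (highest adjusted p 0.0793 for pcx, 0.112 for svr, 0.114 for c11.1, 0.125 for Chc and 0.143 for Moe). Fisher's exact test (two-sided) gave an odds ratio of 4.93 for a call lower on the X in TT-seq (p = 6.39e-63) and 7.33 in total RNA (p = 1.18e-193). For a call higher it was 0.47 by the same exact test (p = 2.79e-07) and 0.33 (p = 1.26e-26). Genes are not independent replicates.

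An index per library, the median X gene minus the median autosomal gene after centring each gene, measured the same difference without the size factors. In TT-seq it was 0.11 ± 0.007 in control libraries and -0.11 ± 0.010 under mof RNAi (SD, n = 4 each), a difference of -0.22 or 0.861-fold (two-sided exact permutation p = 0.0286, the smallest that 70 assignments allow). In total RNA it was 0.12 ± 0.007 and -0.12 ± 0.013, a difference of -0.23 or 0.852-fold (exact permutation p = 0.0286). In each assay the 4 mof RNAi libraries lay below the 4 control libraries, and the Benjamini-Hochberg adjusted value over 12 chromosome tests was 0.049 for each. With a floor of 0.0286, that value depends on how many of the 12 tests reached it. The plot of chromosome indices shows the X and chromosome 4 per library. The arms 2L, 2R, 3L and 3R, each set against the others, changed by less than the X. In TT-seq 3L changed by 0.035 and 3R by -0.022, and in total RNA 2L changed by -0.017 and 3R by 0.012 (exact permutation p = 0.0286, adjusted 0.049 each). The arms 2L (-0.014, p = 0.143) and 2R (0.003, p = 0.629) in TT-seq and 2R (0.006, p = 0.0571) and 3L (-0.004, p = 0.171) in total RNA did not pass the exact permutation test. The X difference was seen in each quartile of expression level. From the lowest to the highest, it was -0.27, -0.24, -0.21 and -0.18 in TT-seq and -0.28, -0.20, -0.22 and -0.23 in total RNA (exact permutation p = 0.0286 each). The highest minus the lowest quartile of level gave 0.089 in TT-seq (exact permutation p = 0.0571, 0.228 adjusted over 4 tests) and 0.045 in total RNA (p = 0.114, adjusted 0.228). The same difference for gene length gave -0.018 (p = 0.371, adjusted 0.495) and 0.006 (p = 0.857, adjusted 0.857), also by exact permutation. The number of X genes that fell in TT-seq depended on single libraries. It was 65 and 162 without control replicates 2 and 3, and 79, 112 and 133 without mof RNAi replicates 2, 3 and 4. The number that rose was 7, 26, 5, 18 and 19 in the same order. In total RNA the number that fell ranged from 554 to 629 when any 1 library was left out.

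**Figure D2:**
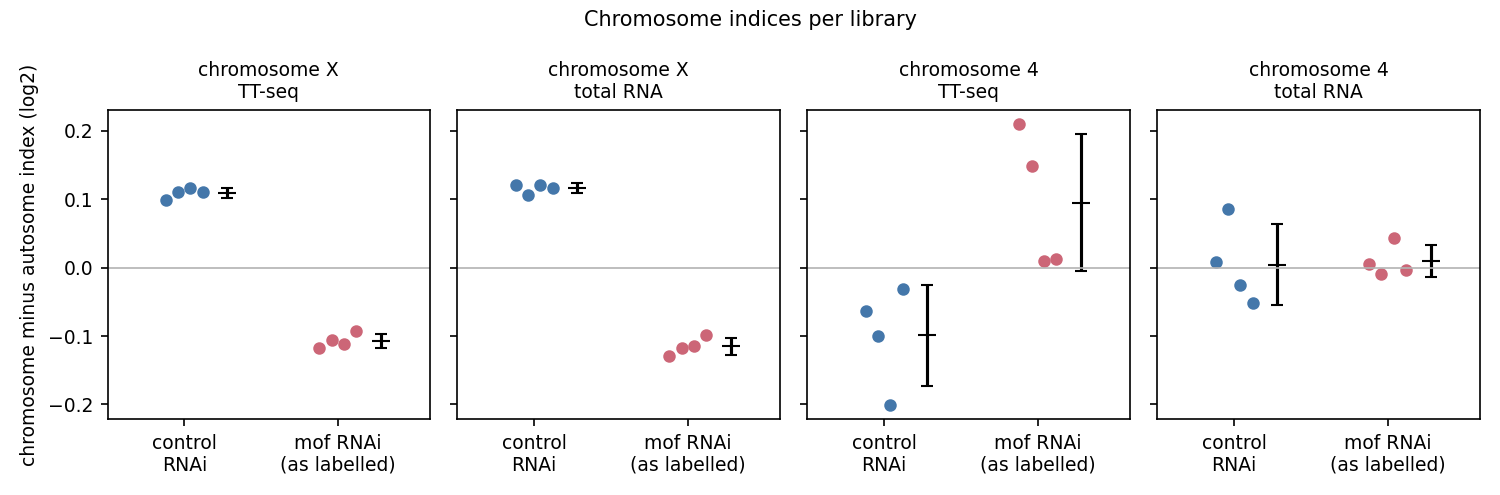
Index of the X and of chromosome 4 per library, for control and mof RNAi libraries of TT-seq and total RNA. It is in log2 units, the median gene of the chromosome minus the median gene of the autosomes. On the X the control libraries average 0.11 and 0.12 and the mof RNAi libraries -0.11 and -0.12, and on chromosome 4 the TT-seq groups average -0.099 and 0.095.

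**Figure D3:**
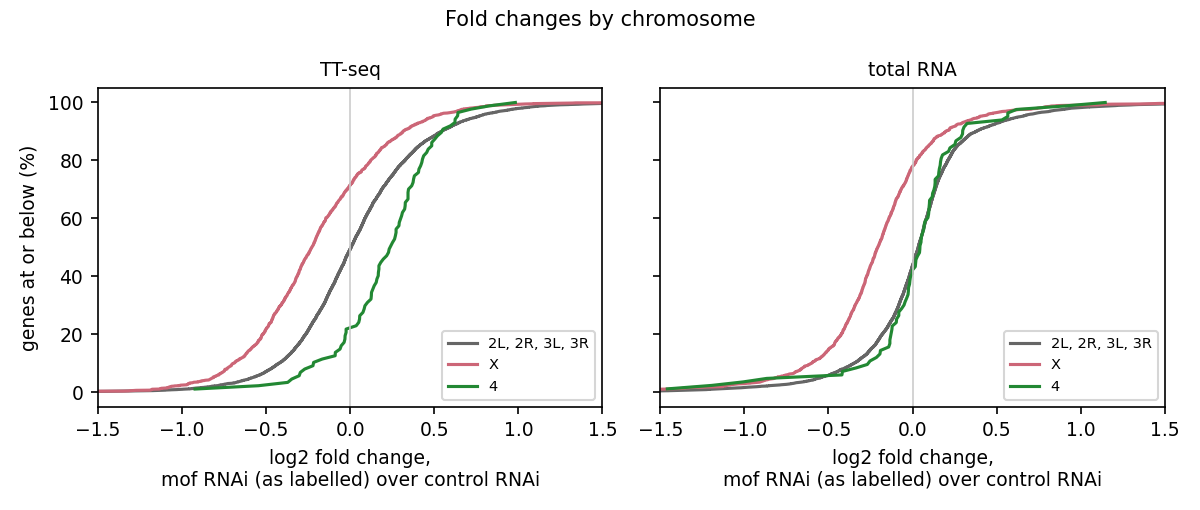
Cumulative share of tested genes by log2 fold change, mof RNAi over control, for 2L, 2R, 3L and 3R together, the X and chromosome 4, in TT-seq (7539, 1569 and 87 genes) and total RNA (7324, 1563 and 83 genes). The X curve is shifted to lower values in both assays, with medians of -0.23 and -0.21 against 0.005 and 0.033 for the autosomes.

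The third comparison asks which genes differed in RNA made during the pulse. In TT-seq the largest rises under mof RNAi among well-counted genes were those of the antisense RNA asRNA:CR43426 (log2 1.97 ± 0.29, adjusted p = 0.00691) and Obp99a, an odorant-binding protein (1.78 ± 0.38, adjusted p = 0.0184). Large rises were also those of St1, a sulfotransferase (1.77 ± 0.18, adjusted p = 0.00261), and Mtkl (1.57 ± 0.32, adjusted p = 0.0159). The largest falls were those of Rpt3R, a paralog of the proteasome ATPase gene Rpt3 (-2.40 ± 0.33, adjusted p = 0.0054), and Hexo1, a hexosaminidase (-1.98 ± 0.28, adjusted p = 0.0054). Among the others were gammaTub37C, the maternal gamma-tubulin (-1.77 ± 0.24, adjusted p = 0.0054), Fign, a microtubule-severing ATPase (-1.61 ± 0.25, adjusted p = 0.0072), and mfas, a fasciclin-type adhesion protein (-1.49 ± 0.18, adjusted p = 0.00409). Rpt3R had 110.5 normalised read counts in control libraries and 21.2 under mof RNAi (n = 4 each). CG17839 (1.75), CG7460 (1.64), lncRNA:CR42715 (1.50) and lncRNA:CR45939 (1.49) were the other large rises, and CG14860 (-1.92), CG7997 (-1.84) and asRNA:CR44807 (-1.56) the other large falls. The values of asRNA:CR43426, Rpt3R, Hexo1, Fign, CG14860 and asRNA:CR44807 are uncertain, since each overlaps a gene on the other strand. So are those of CG7460 and lncRNA:CR45939, which overlap a gene on the same strand. By limma, 499 of 9196 tested genes rose and 543 fell (1042 in all, and 2781 at an unadjusted p under 0.05). With each library centred on its median autosomal gene 403 rose and 620 fell, and with TMM factors 378 rose and 614 fell. The number of calls was 245 without control replicate 2, 659 without control replicate 3, and 264, 463 and 507 without mof RNAi replicates 2, 3 and 4. Of the 53 named genes that passed in TT-seq, 21 kept their calls without any single library, 13 of them in this paragraph. Obp99a, Mtkl and lncRNA:CR42715 lost theirs without control replicate 2 and without mof RNAi replicate 2 (highest adjusted p 0.0666, 0.0591 and 0.0675).

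By the list test, genes of ribosomes, the proteasome, oxidative phosphorylation and heat shock were lower in TT-seq, and immune genes and X-binding factors were higher. Each of these 7 list calls was made with a preset correlation of 0.01 and was lost with an estimated correlation (adjusted p = 0.803 with an estimated correlation). Compared per library after the result was seen, the immune list had an exact permutation p of 0.0286, the smallest that 70 assignments allow. The same test gave 0.114 for mitochondrial ribosomal proteins, 0.457 for cytosolic ribosomal proteins, 0.429 for the proteasome, 0.343 for oxidative phosphorylation and 0.286 for heat shock. These values were not adjusted for the number of lists and assays compared, so none of them is a call. The X-binding factors were not compared in this way. Of 72 tested mitochondrial ribosomal protein genes, 7 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.35 (list test adjusted p = 3.71e-05). The examples were mRpL46 (-1.04), mRpL48 (-0.84) and the X-linked mRpS14 (-1.06). Of 82 cytosolic ribosomal protein genes 0 passed by limma (1 at an unadjusted p under 0.05, 0 by edgeR, 4 by DESeq2; median -0.27, list test adjusted p = 0.0155). Of 31 genes of the proteasome, the protein-degrading complex, 0 passed by limma (2 at an unadjusted p under 0.05, 2 by edgeR, 2 by DESeq2; median -0.21, list test adjusted p = 0.0155). Of 70 genes of oxidative phosphorylation 1 fell and 2 rose, or 1 and 1 adjusted over the list alone (median -0.27, list test adjusted p = 0.0155). Of 15 heat shock genes 3 fell, or 4 adjusted over the list alone (median -0.69, list test adjusted p = 0.0155). They are the small chaperone genes Hsp23 (-1.01) and Hsp27 (-0.69) and the chaperone gene Hsp83 (-0.64, 43123 to 27504 normalised read counts). The median of the heat shock list, centred per gene, was -1.19 and -0.51 in mof RNAi replicates 1 and 2 but 0.20 and 0.30 in replicates 3 and 4, against 0.12 to 0.79 in control libraries. Of 30 immune genes 6 rose and 0 fell, or 12 and 0 adjusted over the list alone (median 0.36, list test adjusted p = 0.000196). They were led by the antimicrobial peptide genes Mtk (1.35, adjusted p = 0.0239), Dro (0.83, adjusted p = 0.0081) and DptB (0.77, adjusted p = 0.0127). Of 11 X-binding factors outside the MSL complex 2 rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.19, list test adjusted p = 0.0468). They are JIL-1, a histone H3 kinase (0.40), and Clamp, which recruits the MSL complex to the X (0.37). The call of Clamp ended with centring on the median autosomal gene and with TMM factors, and each left 1 rise in this list. Of the genes named here Dro and DptB kept their calls without any single library, and the others lost theirs without at least 1, at highest adjusted p-values from 0.0787 (Hsp23) to 0.139 (mRpS14). Without the X-linked members of each list, cytosolic ribosomal proteins (adjusted p = 0.0733), the proteasome (0.06), oxidative phosphorylation (0.13) and the X-binding factors (0.0523, with the same members) did not pass. The TT-seq libraries also differed in how far they leaned towards genes with much total RNA per TT-seq read. The slope of each library on that ratio was 0.14 and 0.29 in control replicates 2 and 3, -0.098 and -0.043 in control replicates 1 and 4, and -0.14 to 0.022 under mof RNAi. The groups differed by -0.14 (exact permutation p = 0.229). The slope is partly built in, since the same TT-seq values form the ratio. Without control replicates 2 and 3, which were left out after the data were seen, the median was 0.33 for the cytosolic ribosomal protein genes (adjusted p = 1.05e-09), 0.091 for the proteasome (adjusted p = 0.183) and 0.12 for oxidative phosphorylation (adjusted p = 0.0977). It was -0.11 for mitochondrial ribosomal proteins (adjusted p = 0.183) and -0.52 for heat shock (adjusted p = 0.051). The immune and X-binding lists kept their calls (adjusted p = 0.0115 and 0.0033), while 82 genes rose and 92 fell. All these list p-values again used the preset correlation of 0.01. For the cytosolic ribosomal protein genes the correlation estimated in the main test was 0.978. Their small p-value therefore overstates the evidence, and a rise of this list is not shown. Leaving out 1 library ended the calls of cytosolic ribosomal proteins (adjusted p = 0.254, 0.959, 0.0524 and 0.0961 without control replicates 2 and 3 and mof RNAi replicates 2 and 3) and of the proteasome (0.0675, 0.596 and 0.0542 without control replicates 2 and 3 and mof RNAi replicate 2). It ended those of oxidative phosphorylation (0.105, 0.488, 0.0524 and 0.0793 without control replicates 2 and 3 and mof RNAi replicates 2 and 3) and heat shock (0.0578, 0.243 and 0.0524 without control replicate 3 and mof RNAi replicates 1 and 2). It also ended the call of the X-binding factors (0.147, 0.0675, 0.103, 0.243 and 0.0524 without control replicates 1, 2 and 4 and mof RNAi replicates 1 and 2).

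**Figure D4:**
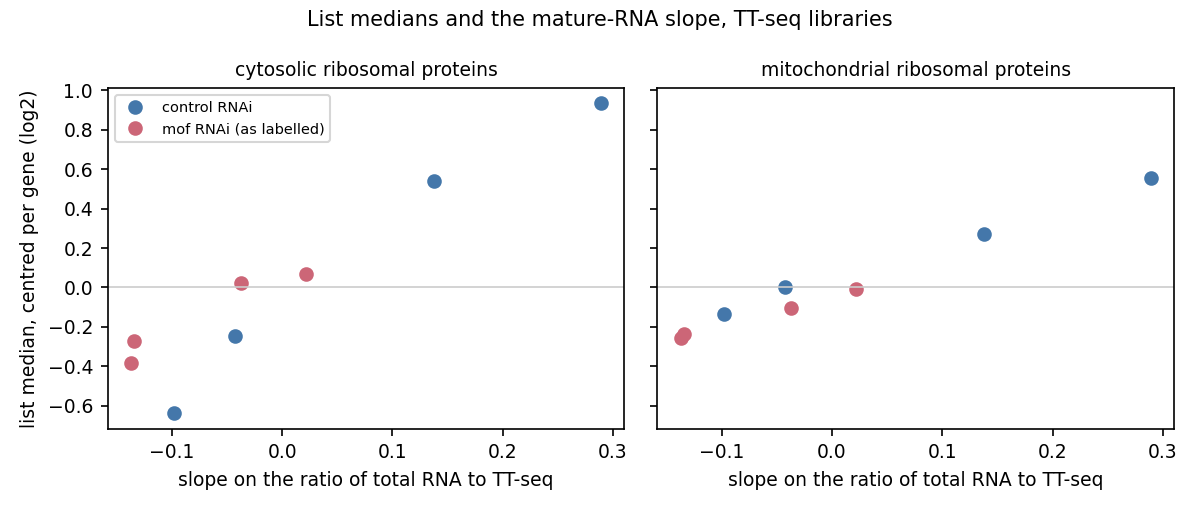
Slope of each TT-seq library on the ratio of total RNA to TT-seq reads per gene, against a list median in the same library (log2 units, centred per gene). The panels show the cytosolic and the mitochondrial ribosomal protein genes, for control and mof RNAi libraries. Control replicates 2 and 3 have slopes of 0.14 and 0.29. Their list values are 0.54 and 0.93 for the cytosolic and 0.271 and 0.555 for the mitochondrial genes. The other libraries have slopes of -0.14 to 0.022.

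Single members of the other lists also passed in TT-seq. In the cell cycle list stg, the Cdc25 phosphatase that starts mitosis, rose by 1.01 ± 0.16 on the log2 scale (adjusted p = 0.0081), and the S-phase activator gene E2f1 rose by 0.59, so that 2 of 28 rose. In the list of apoptosis and DNA damage 4 of 21 genes fell. Among them were the checkpoint kinase genes mei-41 (ATR, X-linked, -0.75, adjusted p = 0.0112) and tefu (ATM, -0.64, adjusted p = 0.00825) and the apoptosome gene Dark (-0.50). Of 14 ecdysone response genes EcR, the ecdysone receptor (0.55), and Eip63E (0.48) rose, or 5 adjusted over the list alone. Of 19 genes of Pol II initiation, pausing and elongation, TH1, a subunit of the pausing factor NELF (-0.58), and Spt6 (-0.52), both X-linked, fell. Nelf-A rose (0.37). Of 22 genes of chromatin acetylation and its readers 2 rose, JIL-1 (0.40) and the H3K9 methyltransferase gene Su(var)3-9 (0.49), or 1 adjusted over the list alone. In the NSL complex nsl1 rose (0.48, 1 of 6), and in the small RNA pathway AGO3 rose (0.45, 1 of 12). In glycolysis the X-linked Hex-A, the hexokinase, fell (-0.45, 1 of 12). Of 12 hemocyte markers the X-linked lz fell (-0.68). Among markers of other cell types, sls rose in muscle (1.33, 1 of 5) and crb in epithelium (0.55, 1 of 7). Of 5 germline, 5 neuron and 3 fat body genes 0 passed by limma (2, 1 and 0 at an unadjusted p under 0.05, 0 by edgeR, and 1, 0 and 0 by DESeq2). Of 7 sex determination and 18 stress genes 0 passed by limma (4 and 2 at an unadjusted p under 0.05, 0 by edgeR, 0 and 1 by DESeq2). The list tests of these lists and of the MSL list, 17 in all, gave adjusted p-values from 0.0949 to 0.859, and their counts were the same adjusted over the list alone where no other is given. The median, mean and test differed in sign for sex determination (median -0.098, mean -0.029, test upward), germline (median -0.23, mean -0.087, test upward) and epithelium (median -0.055, mean 0.077, test upward). In this paragraph stg, mei-41, tefu and sls kept their calls without any single library, and the others lost theirs without at least 1, at highest adjusted p-values from 0.0519 (E2f1) to 0.142 (Su(var)3-9).

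The fourth comparison asks which genes differed in the RNA present in the cells. In total RNA the largest rise under mof RNAi among well-counted genes was that of Nep4, a metallopeptidase (log2 2.89 ± 0.16, adjusted p = 4.51e-11). It went from 88.2 ± 23.7 to 645.2 ± 52.5 normalised read counts (SD, n = 4 each). Among the other large rises were those of Obp99a (2.20 ± 0.19, adjusted p = 4.49e-08) and Picot, a phosphate cotransporter (2.14 ± 0.20, adjusted p = 2.68e-08). So were those of prc, the collagen-like pericardin (1.97 ± 0.31, adjusted p = 5.02e-05), stan, a cadherin of planar polarity (1.93 ± 0.13, adjusted p = 4.3e-10), and the X-linked NetA, an axon guidance netrin (1.80 ± 0.29, adjusted p = 7.97e-05). Among the largest falls were those of CG8301 (-2.52), Gabat, the GABA transaminase (-2.13 ± 0.59, adjusted p = 0.0203), and Rpt3R (-1.80 ± 0.15, adjusted p = 7.28e-09). Others were those of GstE13, a glutathione S-transferase (-1.68 ± 0.14, adjusted p = 1.18e-08), cuff, a factor of the piRNA pathway (-1.64 ± 0.25, adjusted p = 3.51e-05), and the X-linked Appl, the amyloid-precursor-like protein (-1.62 ± 0.21, adjusted p = 6.53e-06). CG17839 (2.32) and CG43179 (2.03) were the other rises of this kind, and CG7997 (-1.96) and asRNA:CR42871 (-1.74) the other falls. The values of prc, CG43179, CG8301, Gabat, Rpt3R, GstE13, cuff and asRNA:CR42871 are uncertain, since each overlaps a gene on the other strand. By limma, 1128 of 8971 tested genes rose and 1286 fell (2414 in all, and 3389 at an unadjusted p under 0.05). With each library centred on its median autosomal gene the share of rises among the calls was 34.6% instead of 46.7%. Of the 81 named genes that passed, 66 kept their calls without any single library, among them all genes of this paragraph.

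By the list test with a preset correlation of 0.01, mitochondrial ribosomal protein, oxidative phosphorylation and heat shock genes were lower in total RNA, and cytosolic ribosomal protein and immune genes were higher. All 5 list calls were lost with an estimated correlation. That gave adjusted p = 0.729 with an estimated correlation for mitochondrial ribosomal proteins and immune genes, 0.809 for oxidative phosphorylation and heat shock, and 0.838 for cytosolic ribosomal proteins. With fry, mitochondrial ribosomal proteins (adjusted p = 0.0231) and immune genes (0.0289) passed. Oxidative phosphorylation (fry adjusted p = 0.0561), heat shock (0.188) and cytosolic ribosomal proteins (0.262) did not. Compared per library after the result was seen, mitochondrial ribosomal proteins and immune genes differed (exact permutation p = 0.0286 each), and cytosolic ribosomal proteins and oxidative phosphorylation (0.0857 each) and heat shock (0.0571) did not. Of 72 mitochondrial ribosomal protein genes 20 fell and 0 rose (median -0.16, list test adjusted p = 0.000474), led by mRpL48 (-0.61, adjusted p = 0.000879), mRpL40 (-0.59, adjusted p = 0.00738) and mRpS9 (-0.49, adjusted p = 1.99e-05). Of 69 genes of oxidative phosphorylation 16 fell and 1 rose (median -0.082, list test adjusted p = 0.00384). They were led by the X-linked complex I genes ND-ASHI (-0.76), ND-24 (-0.65) and ND-18 (-0.54). Without the X-linked members the list did not pass (median -0.061, adjusted p = 0.148). Of 83 cytosolic ribosomal protein genes 20 rose and 10 fell, or 26 and 10 adjusted over the list alone (median 0.094, list test adjusted p = 0.00448). The 10 that fell are X-linked, RpL7A (-0.27), RpS14b (-0.26) and RpL35 (-0.25) among them, and the 20 that rose are among 69 members elsewhere. RpS14b has a near-identical copy, RpS14a, so the reads of either are uncertain. With each library centred on its median autosomal gene, 11 instead of 20 rose and 11 instead of 10 fell. Of 16 heat shock genes 3 fell, Hsp67Ba (-1.66), Hsp70Aa (-1.35) and Hsp70Bbb (-1.23), and Hsf, the heat shock transcription factor, rose (0.16; median -0.58, list test adjusted p = 0.00136). These 4 calls by limma stand beside 11 by edgeR and 5 by DESeq2. Centring on the median autosomal gene left 3 falls and 0 rises. The mof RNAi replicates 1 and 2 carry the fall of the list, with centred medians of -0.83 and -0.72, while replicates 3 and 4 had 0.018 and 0.23 and control libraries 0.082 to 0.66. The Hsp70 genes are near-identical copies, so reads cannot be assigned to either with certainty. Of 32 immune genes 10 rose and 1 fell, or 11 and 2 adjusted over the list alone and 9 and 3 with the same centring (median 0.18, list test adjusted p = 0.00136). They were led by the stress peptide gene TotM (1.06, adjusted p = 0.00989) and the antimicrobial peptide genes Mtk (0.78, adjusted p = 0.00601) and DptB (0.72, adjusted p = 5.49e-06). The list call of the cytosolic ribosomal proteins also ended without mof RNAi replicate 4 (median 0.069, adjusted p = 0.0806). The calls of the 3 heat shock genes that fell ended without control replicate 1, 3 or 4 or mof RNAi replicate 2 and, for Hsp70Bbb, without mof RNAi replicate 1 (highest adjusted p 0.0987, 0.121 and 0.0908).

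In the cell cycle list 7 of 28 genes rose and 2 fell in total RNA. The Cdc25 phosphatase gene stg (0.51, adjusted p = 3.67e-07) and the cyclin-dependent kinase inhibitor gene dap (0.34, adjusted p = 0.00203) rose, and the X-linked cyclin gene CycD fell (-0.44, adjusted p = 5.95e-05). In the list of apoptosis and DNA damage 5 of 21 genes rose and 5 fell in total RNA. Dark (-0.46), the X-linked mei-41 (-0.43) and the TNF gene egr (-0.42) were among the falls. Of 18 genes of oxidative and unfolded protein stress 7 rose and 0 fell, or 4 and 2 with centring on the median autosomal gene. The rises were led by the glutathione synthesis gene Gclc (0.48, adjusted p = 5.38e-08), the metallothionein gene MtnA (0.37, adjusted p = 0.00341) and Pdi, a protein disulfide isomerase (0.19, adjusted p = 0.00546). Of 13 ecdysone response genes 5 rose and 2 fell, with the nuclear receptor gene Hr39 (0.42) and EcR (0.32) among the rises and Eip93F among the falls (-0.52). Of 14 hemocyte markers 5 rose and 2 fell (6 and 2 adjusted over the list alone), with PPO1, a prophenoloxidase, at a low level (2.58), Hml, hemolectin (0.44), and Pxn, peroxidasin (-0.50), changed most. In the list of Pol II initiation, pausing and elongation 4 of 19 rose and 5 fell (5 and 6 adjusted over the list alone), with the TFIIH kinase gene Cdk7 (-0.41), TH1 (-0.38) and NELF-B (-0.37), all X-linked, among the falls. Of 22 genes of chromatin acetylation and its readers 7 rose and 2 fell (8 and 3 adjusted over the list alone), led by Ada2b (0.33), Pof, which binds chromosome 4 (0.28), and Su(var)3-9 (0.27). Of 11 X-binding factors 3 rose and 0 fell, Trl, the GAGA factor (0.29), pzg (0.18) and Top2, topoisomerase 2 (0.16). In the NSL complex nsl1 (0.26) and MBD-R2 (0.14) rose and the X-linked wds fell (-0.23) among 6 genes, or 3 rose and 1 fell adjusted over the list alone. In sex determination 2 of 7 rose and 2 fell. The splicing factor genes snf (-0.36), Sxl (-0.30) and fl(2)d (0.19) changed most, and the 2 that fell, snf and Sxl, are the X-linked members. The proteasome had 2 rises and 2 falls among 31 genes, with the X-linked ATPase genes Rpt4 (-0.31) and Rpt3 (-0.28) and the autosomal Prosbeta1 (0.18). Glycolysis had 3 rises and 1 fall among 12, with Pglym78 (0.34), the X-linked Hex-A (-0.30) and Ald1 (0.19). With centring on the median autosomal gene there were 6 rises and 4 falls in the cell cycle list, 0 and 3 in the proteasome, 1 and 2 in glycolysis, 4 and 3 in chromatin acetylation, and 2 and 6 among the Pol II factors. In the small RNA pathway the piRNA gene aub (-0.51) and the siRNA gene AGO2 (-0.22) fell, 2 of 12. Among markers of other cell types, bam rose at a low level (2.34) and the X-linked Sxl fell in the germline list of 5. In the neuron list of 4 elav rose (0.22), and in the fat body list of 3 the X-linked Ilp6 fell (-0.23). In the epithelium list of 8 crb rose (0.69) and 3 genes fell, all X-linked, sdt (-0.33) and baz (-0.23) among them. Of 4 muscle genes 0 passed by limma (0 at an unadjusted p under 0.05, 0 by edgeR, 0 by DESeq2). These lists and the MSL list, 19 in all, had list test adjusted p-values from 0.11 to 0.939, and the counts were the same adjusted over the list alone where no other is given. Of these, fry passed X-binding factors (adjusted p = 0.0231), chromatin acetylation (0.0289), oxidative and unfolded protein stress (0.0365) and the small RNA pathway (0.042). The median, mean and test differed in sign for hemocyte markers (median -0.025, mean 0.16, test upward), apoptosis and DNA damage (0.033, -0.021, upward), Pol II factors (0.041, -0.043, downward) and epithelium (-0.068, 0.14, downward). The calls of wds, MBD-R2, fl(2)d, Prosbeta1, Ald1, Cdk7, Pof, Su(var)3-9, Trl and elav ended without at least 1 library, at highest adjusted p-values from 0.0579 (Trl) to 0.112 (wds).

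The last comparison sets the assays side by side and asks whether RNA made in the pulse and RNA present in the cells changed alike. Of 8676 genes tested in both, 190 rose in both, where 59.6 would be shared if the calls were independent, and 411 fell in both, where 79 would be. Dyrk2, a protein kinase gene on 2L, was the 1 gene with opposite calls (0.45 in TT-seq and -0.17 in total RNA). Obp99a, Rpt3R, CG17839 and CG7997 stood among the largest changes of both assays. The log2 changes had a Pearson correlation of 0.632 and a Spearman correlation of 0.601 across genes, which are not independent replicates. Of 255 X genes that fell in TT-seq and were tested in both, 223 fell in total RNA too. The X index changed by -0.22 in TT-seq and -0.23 in total RNA over these genes, a difference of 0.016 (exact permutation p = 0.0857, 0.159 adjusted over 13 differences). Libraries of like number were subtracted from each other to form it, although the labels do not say whether the numbers mark pairs. In the heat shock list the medians of mof RNAi replicates 1 and 2 were the lowest in both assays. The cytosolic ribosomal protein list showed no such order. If like numbers of the assays share cultures, neither the tests between assays nor the overlap of calls allows for it. Genes of chromosome 4, the small chromosome bound by Pof, rose in TT-seq by 0.19 relative to the autosomes. Their index went from -0.099 ± 0.073 to 0.095 ± 0.10 (SD, n = 4 each, exact permutation p = 0.0286, 0.049 adjusted over 12 tests). Of 87 tested genes 10 rose and 0 fell, CG11155 (0.83), Mitf (0.60), Dyrk3 (0.50) and Crk (0.44) among them, which were chosen after their values were seen. In total RNA the index of chromosome 4 changed by 0.005 (exact permutation p = 0.914), and 10 of 83 genes rose and 3 fell. The latter are unc-13 (-0.19), Ank (-0.14) and the translation factor gene eIF4G1 (-0.27). The difference of the chromosome 4 index between the assays was 0.20 (exact permutation p = 0.0857, adjusted 0.159). The TT-seq rise did not pass the exact permutation test without control replicate 2 (0.19, p = 0.0571), control replicate 3 (0.15, p = 0.0857) or mof RNAi replicate 1 (0.14, p = 0.0571).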

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

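The tests of mof and of the ribosomal protein genes, and the chromosome 4 test with a covariate, were chosen after the result was seen; the matched-set test of chromosome 4 was chosen before it.

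The gene mof was counted higher in the libraries labelled mof RNAi, by 0.81 in TT-seq and 1.13 in total RNA on the log2 scale. A single exchanged library label is argued against: the X index separated the groups by at least 0.192 in both assays, 21.1 and 20.3 times the SD within groups, although an exchange of both whole groups was not tested. The values that run the way the labels say are the X index, lower under mof RNAi by 0.216 in TT-seq and 0.232 in total RNA, and roX2, lower by 0.86 in total RNA. Reads from the double-stranded RNA trigger counted at mof are a candidate explanation in total RNA. There the spread of mof between the mof RNAi libraries (SD 0.54, against 0.051 in control libraries) lay at percentile 99.9 of genes of like level. In TT-seq it was no wider than in control libraries (SD 0.23 against 0.267, percentiles 74.1 and 79.5). The spread therefore gives no such sign for the TT-seq rise of 0.81. The difference between the assays cannot tell higher transcription of mof apart from trigger reads. The TT-seq change minus the total RNA change was -0.298 with an exact permutation p of 0.457.

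The list of cytosolic ribosomal protein genes was called lower in TT-seq with a preset correlation (median -0.27), but not with an estimated correlation (adjusted p = 0.803), and 0 of 82 members passed by limma (1 at an unadjusted p under 0.05, 0 by edgeR, 4 by DESeq2). Without the X-linked members the median was -0.244 and the call was not made (adjusted p = 0.0733), so they account for little of the median. An unequal share of mature RNA in the TT-seq libraries may account for it: with the slope on the ratio of total RNA to TT-seq reads as a covariate the median was 0.283 (adjusted p = 4.72e-11), and the same covariate moved the proteasome to 0.064 (adjusted p = 0.315), oxidative phosphorylation to 0.11 (adjusted p = 0.139) and mitochondrial ribosomal proteins to -0.13 (adjusted p = 0.18). The covariate comes from the same TT-seq values, and no biological explanation was tested. Compared per library, a test chosen after the result was seen, the list differed by -0.29 (exact permutation p = 0.457), the proteasome by -0.197 (p = 0.429), oxidative phosphorylation by -0.266 (p = 0.343) and mitochondrial ribosomal proteins by -0.326 (p = 0.114), while the immune genes differed by 0.36 (p = 0.0286).

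Genes of chromosome 4 were higher in TT-seq, with an index difference of 0.19. Gene length, level and the ratio of total RNA to TT-seq reads may not be the whole cause. The median of 81 chromosome 4 genes, 0.23, lay at percentile 99.94 of 10000 sets of autosomal genes matched on these properties. The matched sets had a median of 0.097 and a central range of 0.024 to 0.17. That percentile treats genes as independent and takes no account of the spread between libraries, so it cannot exclude these properties. An unequal share of mature RNA stays open, since with the covariate the difference was 0.161 and its exact permutation p was 0.0857. An effect of mof RNAi on chromosome 4 may be the other explanation; it was not tested apart from these.

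In groups of 4 libraries, 15 of 302 groups tested held a value far from the other 3, about the 1 in 20 that chance gives. In TT-seq, Obp99a stood at 143.5 in mof RNAi replicate 1 (others 58.4 to 68.9), mRpL48 at 148.2 in control replicate 3 (92.5 to 94.9), Hsp27 at 4551.9 in control replicate 3 (2896.2 to 3143.4) and Dark at 1583.6 in mof RNAi replicate 1 (2192.7 to 2276.1), all in normalised read counts. In the mof RNAi libraries of total RNA, msl-2 stood at 1671.6 in replicate 2 (1890.4 to 1932.3), nsl1 at 4499.7 in replicate 3 (4894.3 to 4953.8), MBD-R2 at 3851.1 in replicate 3 (3785.6 to 3796), mRpS9 at 779.3 in replicate 2 (880.7 to 883), ND-ASHI at 524.5 in replicate 2 (609 to 617.9) and ND-24 at 451.7 in replicate 3 (587.3 to 604.5). In the control libraries of total RNA, roX1 stood at 27.8 in replicate 2 (51.6 to 56.2), NetA at 50.1 in replicate 3 (22.6 to 26), TotM at 1162 in replicate 2 (1946.8 to 2101.3), Hml at 549.1 in replicate 2 (614.3 to 627.5) and Pof at 540.9 in replicate 2 (462.1 to 469). A difference between the assays' effects was found for the index of 3L (0.042), the index of 3R (-0.031) and roX2 (0.793), each with an exact permutation p of 0.0286 and 0.124 after adjustment over 13 differences.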

How the results depend on the processing

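The covariate, the omission of both control libraries and all alternatives of the chromosome 4 index were chosen after the result was seen. The X index kept its sign under every alternative run, from -0.234 to -0.209 in TT-seq and from -0.235 to -0.226 in total RNA. With a block by replicate number it was -0.216 and -0.232 with an exact permutation p of 0.125, the smallest that 4 differences allow, and the chromosome 4 index was 0.194 with the same p. Libraries of like number were not more alike than others (correlations of -0.261 to -0.154 in TT-seq). This does not settle whether the block marks a shared culture, and the labels do not say. The block gave 8 rises and 5 falls in TT-seq with limma (2082 genes at an unadjusted p under 0.05), with 1 X fall and 0 X rises. Shared by both assays were 6 rises and 5 falls, and total RNA had 2445 calls. DESeq2 gave 895 rises, 851 falls and 74 X rises in TT-seq. A fold change of at least 1.5 left 328 rises and 351 falls in TT-seq (152 and 24 on the X falling and rising) and 193 and 278 in total RNA (110 and 26). Without TT-seq control replicates 2 and 3 there were 82 rises, 92 falls, 42 X falls, 7 X rises and 4 lists called, the X index was -0.22 (exact permutation p = 0.0667, the smallest that 6 libraries allow) and the chromosome 4 index 0.122 (p = 0.133). The chromosome 4 index in TT-seq was 0.162 without a filter (exact permutation p = 0.0571) and 0.161 with the covariate (p = 0.0857), and in total RNA -0.007 with the mean over genes. With an estimated correlation 0 lists were called in either assay, and with fry 0 in TT-seq. In total RNA fry called mitochondrial ribosomal proteins, immune genes, X-binding factors, chromatin acetylation, oxidative and unfolded protein stress and the small RNA pathway (fry adjusted p from 0.0231 to 0.042). The difference of the X index between the assays was 0.025 (exact permutation p = 0.0286) at a mean of at least 50 and -0.002 with the mean over genes. The reversed medians of TT-seq lists, with the covariate and without both control libraries, were 0.283 and 0.331 for cytosolic ribosomal proteins, 0.064 and 0.091 for the proteasome and 0.111 and 0.124 for oxidative phosphorylation; msl-2 turned to 0.125 and 0.139 and roX2 to 0.023 and 0.059. Leaving out 1 library gave 101 to 574 rises, 141 to 642 falls, 65 to 287 X falls, 5 to 52 X rises and 2 to 8 lists called in TT-seq, 0.145 to 0.223 for the chromosome 4 index in TT-seq and -0.012 to 0.034 in total RNA, 0.009 to 0.019 for the difference of the X index, -0.139 to 0.043 for msl-2, -0.015 to 0.556 for roX1 and -0.094 to 0.021 for msl-3 in total RNA. Of these, msl-2 turned sign without control replicate 3, roX1 without mof RNAi replicate 4 and msl-3 without control replicate 1, and the total RNA index of chromosome 4 turned sign without control replicate 3 or 4 or mof RNAi replicate 3. Where no construction such as fewer libraries or genes shows it, the cause was not tested. Small changes can be missed: in TT-seq 27% of simulated 1.5-fold changes were recovered, against 68.8% in total RNA, with genes drawn independently.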

Other observations

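The tests along the X and of roX2, and the division of lists by chromosome, were chosen after the result was seen; the counts over other splits of the libraries were planned before.

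Several of the lists hold both X-linked and autosomal genes, and in total RNA their called members are given by location here, without a test of the difference. Over all tested genes 41.2% on the X and 8.72% on the autosomes fell, and 5.12% and 14.2% rose. In the cytosolic ribosome and the Pol II factors the called members elsewhere rose with the main scaling. In the mitochondrial complexes all but 1 of the called members of both parts fell. Among cytosolic ribosomal protein genes 10 of 14 X-linked members fell and 0 rose, while 20 of 69 members elsewhere rose and 0 fell; with centring on the median autosomal gene these counts were 11 and 11, and with TMM factors 10 and 15. Of the Pol II factors all 5 X-linked members fell, the largest subunit gene Polr2A (-0.26, adjusted p = 0.000156) among them, while 4 of 14 members elsewhere rose and 0 fell, or 2 rose and 1 fell under either of these scalings. In oxidative phosphorylation 9 of 11 X-linked members fell, and elsewhere 7 of 58 fell and 1 rose, or 11 and 0 with centring on the median autosomal gene and 9 and 0 with TMM factors. In the mitochondrial ribosome 8 of 11 X-linked members and 12 of 61 members elsewhere fell.

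Some X genes went the other way. Besides mof, 16 X genes rose in both assays, chosen here after their values were seen, for example Tsf1, a transferrin (0.42 in TT-seq and 0.78 in total RNA), Paics, an enzyme of purine synthesis (0.49 and 0.53), Tbh, the tyramine beta-hydroxylase gene (1.09 and 0.82), and Socs16D (0.35 and 0.32).

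The size of the change may differ between regions of the X. In bins of 2 Mb the median change of X genes minus the autosomal median was below 0 in all 12 bins of both assays, from -0.33 to -0.14 in TT-seq and from -0.33 to -0.17 in total RNA, and the share of 10000 shuffles of genes along the X with as large a variance of the medians was 0.0107 in TT-seq and 0.0028 in total RNA. The shuffles treat genes as independent and take no account of the spread between libraries, so they cannot show that regions differ. No autosome was tested in this way. The lowest bin was 8 to 10 Mb in TT-seq (-0.326) and 22 to 24 Mb in total RNA (-0.333). What the bins have in common was not tested.

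A change after synthesis may account for the fall of roX2 in total RNA, since the TT-seq change minus the total RNA change was 0.793 (exact permutation p = 0.0286). Adjustment over 13 differences gave 0.124. As 0.0286 is the smallest value that 70 assignments allow, 1 difference alone cannot pass this adjustment, whatever its size. Differences of like-numbered libraries were -0.25 to 0.07 in TT-seq and -1.04 to -0.74 in total RNA. The explanation stays open.

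The libraries of each assay can be split into 4 and 4 in 35 ways. For the counts of genes chance can be excluded only at the smallest share possible, 1 of 35, and a split that mixes the groups gives few calls because their difference enters its spread. The real split alone reached 499 rises, 543 falls, 256 X falls and 45 X rises in TT-seq, with at most 0 in the other splits, and it alone reached 1128 rises, 1286 falls, 644 X falls and 80 X rises in total RNA, with at most 1 in the others. For the number of lists called chance cannot be excluded: 19 splits reached the 7 lists of TT-seq, with up to 10 in another split, and 9 splits reached the 5 lists of total RNA, with up to 6.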
